A study of Mus musculus with 6 samples.

How the data were processed

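RNA was sequenced from 6 libraries of regulatory T cells (Tregs, the FOXP3-expressing CD4 T cells that restrain immune responses) of C57BL/6 mice aged 3 months. Per the labels, 3 libraries came from mice that carried the Foxp3-YFP-Cre allele with unaltered Junb (WT) and 3 from mice in which the same Cre allele acted on floxed Junb (KO). Cre made under Foxp3 removes floxed sequence in Tregs. The Tregs were sorted by flow cytometry, per the labels' protocols, and the sorting gate is not given in the sources used here. RNA was extracted with a QIAGEN RNeasy kit, freed of DNA and turned into libraries with the SMARTer ultra-low-input RNA kit and the NEBNext ChIP-Seq kit, per the labels' protocols. Single reads of 50 bases were taken on an Illumina HiSeq instrument, with 6 libraries in a lane. The labels name no molecular identifiers, so PCR copies of a molecule are counted as separate reads. The interval given for Junb comes from the edgeR fit described below. The variance of that fit holds the spread between libraries as well as counting error, and draws on other genes.

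The authors deposited 1 table of raw read counts per library, with 1 row for each of 53379 Ensembl gene identifiers. Per the submitters' processing notes, bcl2fastq 2.19.0.316, STAR 2.3 and featureCounts were used with the mouse genome build mm10. The annotation release, the version and options of featureCounts and the use of strand are not given in the sources used here. The deposited counts show how reads of several places were treated. The mitochondrial gene mt-Co3 and its nuclear copy Gm28437 differed by at most 2 counts in each library, and 38 genes with 1000 or more counts in all had the same count as another gene in all 6 libraries. Reads that align to near-identical copies were therefore counted at each copy. Fen1 and the antisense gene Gm10143, which overlap, had similar CPM in each library, such as 30.8 and 30.1 CPM in WT replicate 1. Counts of copies, overlapping genes and antisense genes were treated as uncertain. Of the 61 genes that the naming rule gave, 26 overlap another annotated gene and 0 had counts identical to another gene.

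Gene symbols, positions and types were taken from GENCODE M21 on GRCm38, the assembly that mm10 also names. Of the 53379 identifiers, 53274 were matched without their version number and 105 were not. Library totals lay between 33784183 and 41231173 counts. The spread between libraries limited the comparisons: the common dispersion was 0.260, a coefficient of variation of 51.0% between libraries of a genotype. How far depth limited them was not tested. All pairs of libraries differed by 38.3 to 142 times the chi-square per degree of freedom that sampling noise gives, over genes with at least 10 counts in the pair, so no library was a copy of another. The closest pair was WT replicate 2 and KO replicate 2, and pairs of a genotype lay between 66.4 and 142.

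The design, the tests, the gene lists, the naming rule and most alternatives were fixed before the data were examined. The submitters' text, which says that genes enriched in Tregs were lower without JunB, was known by then. The Treg signature list was tested for that reason, so its direction was not an independent prediction. Counts were compared between KO and WT with edgeR 4.0.16 (R 4.3.3): filterByExpr, TMM factors, a robust quasi-likelihood fit with genotype as the only term, a two-sided F test and Benjamini-Hochberg adjustment, with a threshold of 0.05 on the adjusted p. After the filter 20475 genes were tested. Log2 fold changes are KO minus WT, with the standard error that the F statistic gives. CPM values use the TMM library sizes and are given as mean ± SD over 3 libraries. The labels do not say that the libraries of a genotype came from separate animals, so p-values measure the spread between these libraries, which may in part be technical.

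In all, 25 gene lists were fixed from textbook knowledge: Treg signature genes, Treg suppressor effectors, effector Treg genes, resting Treg genes, AP-1 family genes, helper T cell cytokines and regulators, IL-2 and STAT5 pathway genes, T cell receptor (TCR) early response genes, heat shock genes, proliferation genes, interferon-stimulated genes, genes induced by interferon gamma, migration receptors, costimulatory and coinhibitory receptors, glycolysis genes, cholesterol synthesis genes, BCL2 family and related apoptosis genes, TGF-beta pathway genes, and markers of B cells, plasma cells, myeloid cells, CD8 T and NK cells, conventional CD4 T cells, erythroid cells and platelets, and all T cells. Of 606 entries 604 were matched and 585 were tested. Each list was tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, which compares its members with all other genes, and adjusted over the 25 lists. Camera was repeated with the correlation estimated from the data. Fry was run as another test, of whether the genes of a list move one way on balance, and it does not compare them with other genes. The score of a list in a library is the mean of log2(CPM + 1) over its tested members, compared between genotypes with an exact two-sided permutation test, whose smallest p for 3 against 3 libraries is 0.1. Counts of list members past the threshold are from edgeR, adjusted over all genes and adjusted over the list alone. Among list members DESeq2 without a pool term called only Junb, Ltbp4 and Gp9 over all genes.

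The naming rule gave Junb, Foxp3, Il2ra, Ctla4 and Ikzf2, then genes past the threshold with a mean of at least 5 CPM and no overlap between genotypes, up to 10 in each direction by fold, leaving out predicted genes, pseudogenes and immunoglobulin and T cell receptor segments. Where fewer than 5 passed in a direction it was filled to 5 by the smallest unadjusted p under the same rule. Of each list it gave up to 4 members past the threshold, and the 2 with the highest mean CPM where fewer than 2 passed. Some genes that the rule gave are not reported here.

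On simulated counts with the means, library sizes and dispersions of the KO against WT comparison (20475 genes, 200 changed), edgeR recovered 0% of 2-fold, 43% of 4-fold and 59% of 8-fold changes. Among genes of at least 5 CPM the shares were 1.5%, 72% and 91%. DESeq2 recovered 27%, 63.5% and 77% with 71, 91 and 83 false calls, and 42%, 90% and 98.5% among genes of at least 5 CPM with 88, 75 and 112 false calls, where edgeR made at most 9. With no change simulated, edgeR made 0 calls and DESeq2 1.42.0 made 55. The dispersions were those that edgeR estimated and the genes were simulated as independent. These rates therefore need not hold for DESeq2 on the real, unfiltered counts. With the Treg signature list shifted by -0.5 (log2) in simulated independent genes, camera called it and 6 other lists, of which 5 share genes with it. With no change simulated, also in independent genes, it called 1 of the 25 lists. In the real data the estimated correlation between genes of a list lay between -0.031 (AP-1 family) and 0.919 (B cell markers). The simulation therefore gives no rate of false list calls for the real data, where splits other than by genotype gave 4 to 14 calls.

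The alternatives were RLE size factors, library size alone, no filter on low counts, a filter of 1 CPM in 3 libraries, DESeq2, limma-voom, the replicate number as a block, the inferred sequencing pool as a term, each library left out in turn, for lists an estimated correlation, fry and members of 1 list only, and for library shares a denominator without mitochondrial counts. The 2 pools are an inference: a number in the names of the deposited count tables was taken to mark a sequencing pool, and the labels do not say what it marks. It puts WT replicates 1 and 2 and KO replicate 2 in pool A, and WT replicate 3 and KO replicates 1 and 3 in pool B. All values within pools and with a pool term rest on this reading. Library quality weights in limma-voom, a covariate for B cell genes, the removal of 105 tested genes with identical counts, DESeq2 with a pool term, and the pool term with an estimated correlation were chosen after seeing the data.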

Results

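Tregs labelled as WT or as KO for JunB, a subunit of the AP-1 transcription factor that T cells raise after stimulation, were compared in 6 libraries. WT and KO had 3 libraries each, all with a total between 33784183 and 41231173 counts. Between 25697 and 26438 genes had at least 1 count in a library. The comparison addressed which genes depend on JunB in Tregs, and whether genes enriched in Tregs are among them. The KO libraries had 64.5% of the WT level of Junb, a lower mean of most Treg signature and T cell receptor response genes, and a higher mean of most markers of B, myeloid and conventional CD4 T cells. Over all genes edgeR called 0 genes (590 at an unadjusted p under 0.05), limma-voom 0 (750 unadjusted) and DESeq2 63. By camera at a preset correlation 16 of the 25 gene lists passed, and all 16 calls were lost with an estimated correlation (smallest adjusted p = 0.408). By fry, which tests a list against no change and not against other genes, 0 lists passed (smallest adjusted p = 0.285).

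Junb (ENSMUSG00000052837.6) lies on chromosome 8, positions 84974484 to 84978718, on the minus strand of GRCm38. Its coding transcript Junb-201 is a single exon (84976910 to 84978718) with the coding sequence at 84977398 to 84978429. A non-coding transcript, Junb-202, has exons at 84976224 to 84976542 and 84974484 to 84974656, and the 173 bases of the latter also lie in the last exon of Prdx2, which runs the other way. Junb stood at 87.1, 77.5 and 89.5 CPM in WT replicates 1 to 3 and at 57.1, 57.3 and 49.6 CPM in KO replicates 1 to 3. The means were 84.7 ± 6.32 CPM in WT and 54.7 ± 4.38 CPM in KO (SD, n = 3, as for all means given), and no KO library reached the lowest WT library. The log2 difference was -0.63 (SE 0.13, 95% interval -0.93 to -0.33). The exact two-sided permutation p was 0.1, the smallest that 3 against 3 libraries can give. The edgeR p was 0.00163 before adjustment and 0.9999 after it, and DESeq2 called Junb with an adjusted p of 0.00412. The sequencing pool is inferred from a number in the names of the deposited tables. Within pool A so inferred (2 WT, 1 KO) the log2 difference was -0.52, and within pool B (1 WT, 2 KO) it was -0.75. Counts per gene do not show which part of Junb the reads in KO came from.

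**Figure D1:**
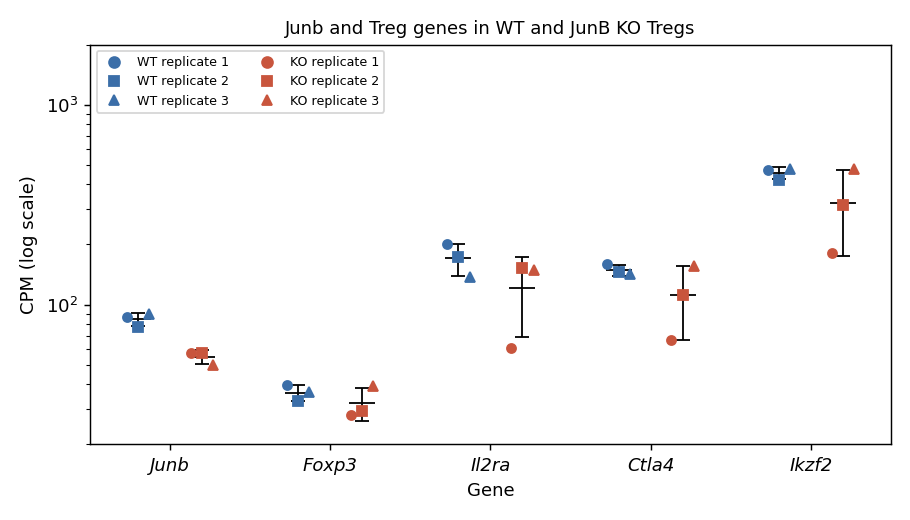
CPM on a log axis of Junb, Foxp3, Il2ra, Ctla4 and Ikzf2 in each library, with WT in blue, KO in red, a symbol per replicate number and black bars for mean ± SD (n = 3). Junb is the 1 gene of these 5 whose WT and KO libraries do not overlap, and KO replicate 1 is the lowest library for Foxp3, Il2ra, Ctla4 and Ikzf2.

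None of the genes with the smallest p and no overlap between genotypes passed the edgeR test, so they are given as values. The higher ones in KO were Fen1, a flap endonuclease of DNA replication (29.3 ± 2.68 and 53.6 ± 3.74 CPM in WT and KO), and Plcl2, a phospholipase C-like protein (15.2 ± 4.23 and 31.0 ± 2.77 CPM). Also higher were Sh3bp5, a partner of the BTK kinase (21.2 ± 1.93 and 34.4 ± 4.68 CPM), the zinc finger gene Zc3h6 (4.38 ± 0.697 and 11.1 ± 3.58 CPM) and Slc25a51, the mitochondrial NAD carrier (33.3 ± 7.30 and 56.2 ± 3.70 CPM). Fen1 overlaps the antisense gene Gm10143 on chromosome 19, so its value is uncertain. Sh3bp5, Zc3h6 and Slc25a51, and of the lower genes below Junb and Vsig10, also overlap another annotated gene and share this limit. The lower ones were Podnl1 (34.6 ± 12.5 and 10.4 ± 0.894 CPM), the cytokine receptor kinase Jak2 (68.9 ± 2.2 and 45.1 ± 2.10 CPM), Ap5z1, a subunit of the AP-5 adaptor (34.8 ± 5.98 and 17.2 ± 1.94 CPM), Junb, and Vsig10 (8.56 ± 1.91 and 2.92 ± 0.525 CPM). Their log2 differences were 0.87, 1.02, 0.70, 1.35 and 0.76 for the higher genes in that order, and -1.73, -0.61, -1.02, -0.63 and -1.55 for the lower. Of 20475 genes tested with edgeR, 0 passed an adjusted p of 0.05, 590 had an unadjusted p under 0.05 (287 higher, 303 lower) and 1024 would by chance. The 3 WT and 3 KO libraries did not overlap in 7.76% of genes, where chance gives 10%. DESeq2, without the edgeR filter, called 63 of 32774 genes (35 higher, 28 lower), of which 9881 had no adjusted p and could not be called. Among the 63 were Fen1, Plcl2, Podnl1, Jak2, Ap5z1, Junb and Vsig10. Of the 63 calls, 42 had a mean count under 100 and 32 a log2 difference of more than 4 in either direction. By limma-voom 0 genes were called, with 750 unadjusted. On simulated counts of this comparison, over the 20475 filtered genes with 200 changed 2-fold, edgeR recovered 0% of them with 0 false calls and DESeq2 27% with 71 false calls. Those counts were drawn with edgeR dispersions and independent genes, so they do not compare the 2 tools on neutral ground.

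Most genes that mark Tregs had lower means in KO. Of 55 Treg signature genes 49 were lower and 6 higher, with a median log2 difference of -0.44, a fold of 0.736. Foxp3, the gene of the factor that defines the lineage, stood at 36.3 ± 3.41 and 32.2 ± 5.97 CPM in WT and KO with overlapping libraries. The high-affinity IL-2 receptor chain Il2ra (170.4 ± 31.2 and 121 ± 52.2 CPM), the inhibitory receptor Ctla4 (149 ± 9.45 and 112 ± 45.1 CPM) and Ikzf2, which encodes the Treg factor Helios (456 ± 29.8 and 324 ± 148 CPM), had lower means with overlapping libraries. The log2 differences of Foxp3, Il2ra, Ctla4 and Ikzf2 were -0.17 (SE 0.18), -0.50 (SE 0.35), -0.42 (SE 0.29) and -0.49 (SE 0.32). The most abundant members of the list were the folate receptor Izumo1r (729 ± 87.4 and 494 ± 175 CPM) and the IL-2 receptor chain Il2rb (449.8 ± 30.0 and 355 ± 129.98 CPM). No overlap between genotypes was found for 9 members, all lower in KO and named here after their values were seen: Plagl1, Il10, Ccr8, Gpr83, Tnfrsf1b, Cd83, Cd81, Tigit and Capg. By edgeR none of the 55 passed adjusted over all genes, and 0 passed adjusted over the list alone.

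As a list, the Treg signature genes fell by camera at the preset correlation (adjusted p = 2.4e-16). Camera at that preset also called the list, in either direction, in every other split of the 6 libraries into 3 and 3. The smallest adjusted p of those splits was 5.7e-10 and the largest 0.0331, so such a call is not particular to genotype. The genotype call was lost at adjusted p = 0.494 with the correlation between genes estimated at 0.403. Fry, a test against no change, gave adjusted p = 0.607. The score of the list was 5.73, 5.74 and 5.67 in WT replicates 1 to 3 and 4.72, 5.48 and 5.55 in KO replicates 1 to 3, so every KO library lay below every WT library (exact permutation p = 0.1, the smallest possible). KO replicate 1 had the lowest score, and without it the median was -0.19 (adjusted p = 7.1e-05). It also had the highest score of conventional CD4 T cell markers, 6.16 where the WT libraries had 5.47, 5.38 and 5.26. The score difference was -0.25 within pool A and -0.54 within pool B, and 34 of the 55 genes stand in another of the lists.

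**Figure D2:**
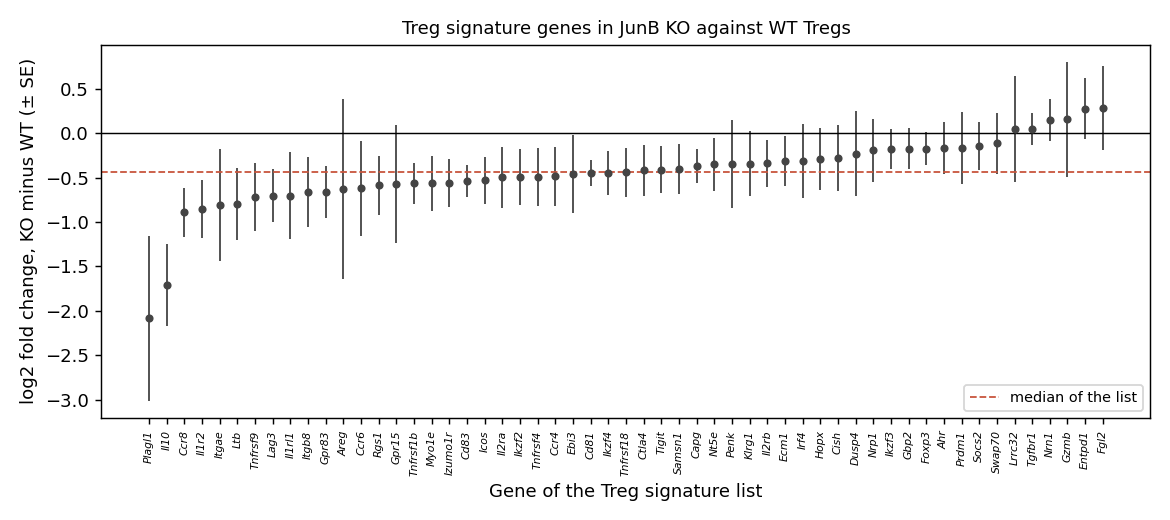
Log2 fold change (KO minus WT, with SE) of each of the 55 Treg signature genes in order of size. The dashed line is their median of -0.44, and 49 of the 55 lie below 0.

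Most effector Treg genes and costimulatory and coinhibitory receptors, and 14 of 23 suppressor effectors, had lower means in KO. Of 40 effector Treg genes 33 had lower means (median log2 difference -0.35), with the TNF receptor family members Tnfrsf4 (OX40, 372 ± 36.8 and 265 ± 118 CPM in WT and KO) and Tnfrsf18 (GITR, 319 ± 59.7 and 235 ± 85.6 CPM) the most abundant. Of 28 costimulatory and coinhibitory receptors 22 had lower means (median -0.22), led in abundance by the CD166 receptor Cd6 (492 ± 59.1 and 436 ± 79.4 CPM) and Tnfrsf4. The suppressor effectors had a median of -0.19, with Icos (246 ± 48.7 and 171 ± 58.1 CPM) and Pdcd1, the gene of PD-1 (229 ± 25.2 and 169.9 ± 35.0 CPM), the most abundant. Of 27 resting Treg genes 17 had higher means (median 0.22), while the factor Tcf7 (372 ± 16.9 and 449 ± 124 CPM) overlapped between genotypes. The score of resting Treg genes was 6.44, 6.41 and 6.40 in WT replicates 1 to 3 and 6.88, 6.59 and 6.25 in KO replicates 1 to 3. That of conventional CD4 T cell markers, which share Tcf7, Il7r and other members with it, was 6.16, 5.71 and 5.18 in the same KO libraries. Camera gave adjusted p = 9.8e-06 for effector Treg genes, 7.9e-05 for costimulation, 0.0103 for suppressor effectors and 0.0327 for resting Treg genes. With an estimated correlation the adjusted p was 0.494 for each of these 4 lists, and 0 of their members passed by edgeR, adjusted over all genes or adjusted over the list alone. Without KO replicate 1 none of the 4 passed: the median was -0.13 (adjusted p = 0.0807) for effector Treg genes, -0.12 (0.476) for costimulation, 0.044 (0.778) for suppressor effectors and -0.024 (0.972) for resting Treg genes. The suppressor call also ended without WT replicate 2 (median -0.26, adjusted p = 0.377), with a pool term (median -0.20, adjusted p = 0.0983) and with library quality weights (median -0.30, adjusted p = 0.0621). The suppressor median was -0.32 with limma-voom, -0.33 with the replicate number as a block and -0.13 with a filter of 1 CPM in 3 libraries. It was -0.30 without WT replicate 1, -0.38 without WT replicate 3, -0.12 without KO replicate 2 and -0.56 without KO replicate 3. The resting call also ended without WT replicate 2 (median 0.11, adjusted p = 0.264), without WT replicate 3 (median 0.19, adjusted p = 0.0680), without KO replicate 2 (median 0.23, adjusted p = 0.0636) and with a pool term (median 0.16, adjusted p = 0.0860). It ended with limma-voom (median 0.13, adjusted p = 0.0707) and library quality weights (median 0.066, adjusted p = 0.260) as well, and its median was 0.12 with the replicate number as a block. The effector median was -0.21 without WT replicate 3, and the costimulation median was -0.12 without WT replicate 1 and -0.35 without KO replicate 2. Within pools A and B the score difference was -0.11 and -0.47 for effector Treg genes, -0.10 and -0.18 for costimulation, -0.044 and -0.094 for suppressor effectors, and 0.17 and 0.16 for resting Treg genes. In genes of 1 list only, the calls ended for effector Treg genes (11 genes, median -0.065, adjusted p = 0.713), costimulation (15 genes, median -0.048, adjusted p = 0.320) and resting Treg genes (14 genes, median 0.039, adjusted p = 0.826). Only 1 suppressor effector stands in no other list, so that list could not be tested in this way.

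Most genes that T cell receptor signals induce had lower means in KO, and 0 of them passed on their own by edgeR. Of 28 TCR early response genes 24 had lower means, with a median log2 difference of -0.31. The most abundant were the NF-kappaB inhibitor Nfkbia (396 ± 19.98 and 325 ± 47.6 CPM in WT and KO) and the mRNA decay factor Zfp36 (219.7 ± 28.8 and 205 ± 33.5 CPM). No overlap was found for Fos, Jun, Egr1, Tnfaip3, Nfkbiz and Nfkbia, lower in KO, or for Myc and Ier3, higher in KO, all but Nfkbia chosen after their values were seen. Of 22 AP-1 family genes 14 had lower means (median -0.28), with Maf (251 ± 55.1 and 196 ± 75.9 CPM) and the JunB partner Batf (90.4 ± 12.6 and 58.8 ± 15.1 CPM) the most abundant. Of 16 helper cytokine and regulator genes 11 had lower means (median -0.21), with Gata3 at 229.7 ± 36.7 and 188 ± 42.8 CPM and Stat6 at 188 ± 12.2 and 187 ± 39.4 CPM. Of 18 genes of the IL-2 and STAT5 pathway 11 had lower means (median -0.12), with the receptor chain Il2rg at 913 ± 121 and 838 ± 120.3 CPM and the kinase Jak1 at 398 ± 30.6 and 408 ± 19.6 CPM. By camera the TCR early response list (adjusted p = 2.2e-06) and the AP-1 list (0.00805) fell, each with an adjusted p of 0.408 with an estimated correlation. The AP-1 list holds Junb, the gene altered in KO, so part of the fall of that list follows from the design. The list was not tested with Junb alone removed. The cytokine list (adjusted p = 0.0620, and adjusted p = 0.494 with an estimated correlation) and the IL-2 list (adjusted p = 0.124, and adjusted p = 0.555 with an estimated correlation) did not pass. By edgeR Junb passed in the AP-1 list and 0 genes in the other 3 lists, adjusted over the list alone, and 0 passed adjusted over all genes, where DESeq2 called Junb. Without KO replicate 1 the TCR median was -0.17 (adjusted p = 0.00357). The AP-1 call ended without KO replicate 1 (median -0.22, adjusted p = 0.0803), without WT replicate 2 (median -0.16, adjusted p = 0.113) and in the 17 of its genes that stand in no other list (median -0.14, adjusted p = 0.451). Its median was -0.18 with the B cell covariate. The cytokine list passed with limma-voom (median -0.23, adjusted p = 0.0343), and its median was -0.026 without KO replicate 1, -0.031 without WT replicate 1, -0.12 without WT replicate 2 and -0.13 with a pool term. The IL-2 list passed without WT replicate 3 (median -0.054, adjusted p = 0.0376), without KO replicate 3 (median -0.17, adjusted p = 0.0149) and with library quality weights (median -0.13, adjusted p = 0.0396). Its median was -0.0023 without KO replicate 1, -0.024 without KO replicate 2, -0.074 without WT replicate 1, -0.19 with a pool term, -0.057 in the 9 of its genes that stand in no other list and 0.014 with the B cell covariate. The TCR score difference was -0.25 within pool A and -0.38 within pool B, and that of the AP-1 list -0.15 and -0.10. TCR scores were 5.06, 4.85 and 5.05 in WT replicates 1 to 3 and 4.51, 4.71 and 4.83 in KO replicates 1 to 3. Scores of conventional CD4 T cell markers were 5.47, 5.38 and 5.26 in WT and ran the other way in KO, at 6.16, 5.71 and 5.18. Whether such cells account for the lower TCR scores was not tested.

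Most interferon response genes had lower means in KO. Of 30 interferon-stimulated genes 24 were lower (median log2 difference -0.26), with Ifi27l2a (321 ± 25.8 and 245 ± 52.0 CPM in WT and KO) among the most abundant. Of 27 genes induced by interferon gamma 25 were lower (median -0.17), with the immunoproteasome subunit Psmb8 (521 ± 33.7 and 483 ± 57.2 CPM) and the GTPase Tgtp2 (297 ± 75.3 and 274 ± 22.0 CPM) overlapping between genotypes. Both lists fell by camera (adjusted p = 0.000322 and 0.00332), with an adjusted p of 0.494 for both with an estimated correlation and 0 members past the threshold by edgeR, adjusted over all genes or adjusted over the list alone. Neither kept its direction in both pools: the score difference of the interferon-stimulated list was -0.16 in pool A and 0.011 in pool B, that of the interferon gamma list -0.16 and 0.085. With a pool term both had an adjusted p of 0.254 (medians -0.072 and -0.074). The first call ended without WT replicate 2 (median -0.085, adjusted p = 0.365) and without KO replicate 1 (median -0.19, adjusted p = 0.0901), and its median was -0.41 without WT replicate 3. The interferon gamma call ended without WT replicate 1 (median -0.073, adjusted p = 0.190), without WT replicate 2 (median -0.13, adjusted p = 0.263) and without KO replicate 1 (median -0.041, adjusted p = 0.778), and its median was -0.31 without WT replicate 3.

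Of 40 proliferation genes 29 had higher means in KO (median log2 difference 0.13, camera adjusted p = 0.0360, and adjusted p = 0.676 with an estimated correlation). The replication genes Mcm6 (91.2 ± 16.3 and 89.5 ± 16.6 CPM in WT and KO) and Pcna (87.2 ± 13.7 and 76.5 ± 12.8 CPM) were its most abundant members. Scores of the list were 4.04, 4.13 and 4.77 in WT replicates 1 to 3 and 4.76, 4.70 and 4.05 in KO replicates 1 to 3. Those of erythroid and platelet markers were 2.59, 3.58 and 5.45 in WT and 6.54, 5.08 and 2.16 in KO. Both were thus highest in WT replicate 3 and KO replicates 1 and 2, and a part of such cells in the proliferation score was not tested. The proliferation score was higher in KO within pool A (0.61) and lower within pool B (-0.36). Its call ended with a pool term (median 0.11, adjusted p = 0.266), with the replicate number as a block (median 0.17, adjusted p = 0.0723), with limma-voom (median 0.12, adjusted p = 0.0772) and without WT replicate 1 (median -0.035, adjusted p = 0.900). It ended also without WT replicate 2 (median -0.0088, adjusted p = 0.707), without KO replicate 1 (median -0.0093, adjusted p = 0.857) and without KO replicate 2 (median 0.019, adjusted p = 0.506). With the lists limited to genes of 1 list only, which removed none of its genes, its adjusted p was 0.0577. The proliferation median was 0.48 without WT replicate 3, 0.37 without KO replicate 3, 0.24 with library quality weights and 0.34 with the B cell covariate. The lists of heat shock, migration, glycolysis, apoptosis, cholesterol synthesis and TGF-beta genes did not pass. The median was -0.16 (adjusted p = 0.0620) for 10 heat shock genes, with the chaperones Hspa8 at 1404 ± 179 and 1158 ± 273 CPM and Hsp90ab1 at 1004 ± 72.7 and 888 ± 75.6 CPM. It was -0.10 (0.123) for 33 migration receptors, with the P-selectin ligand Selplg at 472 ± 19.1 and 440.1 ± 18.3 CPM. It was -0.062 (0.152) for 21 glycolysis genes, with Eno1 at 553 ± 74.7 and 514 ± 67.5 CPM and Aldoa at 515 ± 30.8 and 504 ± 7.52 CPM. Apoptosis genes had a median of -0.095 (0.219, 24 genes), with the survival factors Mcl1 at 199.5 ± 30.1 and 185 ± 38.4 CPM and Bcl2 at 165 ± 41.0 and 170.0 ± 15.8 CPM. For 23 cholesterol synthesis genes the median was -0.049, the mean 0.0090 and the sign of the test negative (0.765), with Sc5d at 56.1 ± 15.2 and 71.1 ± 33.0 CPM and Ebp at 56.1 ± 6.81 and 54.8 ± 5.93 CPM. For 18 TGF-beta pathway genes the median was 0.047, the mean -0.075 and the sign of the test negative (0.856), with Skil at 104 ± 13.2 and 104 ± 6.00 CPM and the receptor Tgfbr2 at 91.9 ± 8.18 and 112 ± 8.51 CPM.

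In that list Ltbp4, a TGF-beta binding protein of the matrix, passed by edgeR adjusted over the list alone (2.91 ± 0.981 CPM in WT and 0.120 ± 0.0606 CPM in KO) and did not pass adjusted over all genes. DESeq2 called Ltbp4 over all genes (log2 -4.61, adjusted p = 7.4e-06). In the proliferation, heat shock, migration, glycolysis, apoptosis and cholesterol lists 0 genes passed either way by edgeR. Over all 6 libraries with an estimated correlation the adjusted p was 0.494 for heat shock, 0.494 for migration and 0.536 for apoptosis genes. The heat shock list passed without WT replicate 3 (median -0.20, adjusted p = 0.0493), without KO replicate 2 (median -0.25, adjusted p = 0.00754), with limma-voom (median -0.19, adjusted p = 0.0481) and with library quality weights (median -0.24, adjusted p = 0.00914). Its median was -0.040 without KO replicate 3 and -0.10 with a pool term. The migration list passed without WT replicate 3 (median -0.18, adjusted p = 0.0457) and with the B cell covariate (median -0.12, adjusted p = 0.0271), and the apoptosis list without KO replicate 3 (median -0.17, adjusted p = 0.0321). With a library left out the median lay between -0.18 and -0.048 for migration, -0.17 and -0.025 for apoptosis, and -0.10 and -0.024 for glycolysis. The glycolysis median was -0.0017 and the apoptosis median -0.18 with a pool term. The TGF-beta median was -0.012 with the replicate number as a block and -0.068 with library quality weights.

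Markers of cells other than Tregs varied widely between libraries and most had higher means in KO. B cell markers were higher for 16 of 18 genes (median log2 difference 0.40), with the immunoglobulin genes Igkc at 3670.5 ± 3176 and 4413 ± 2438 CPM and Ighm at 3824 ± 3167 and 4201 ± 1734 CPM in WT and KO. Myeloid markers were higher for 20 of 21 genes (median 0.78), with lysozyme (Lyz2) at 259 ± 272 and 439 ± 215 CPM and cystatin C (Cst3) at 115 ± 39.4 and 138 ± 21.5 CPM. CD8 T and NK cell markers were higher for 14 of 16 genes (median 0.56), with the chemokine Ccl5 at 147 ± 62.9 and 218 ± 29.3 CPM and Nkg7 at 43.8 ± 5.96 and 73.8 ± 51.3 CPM. Conventional CD4 T cell markers were higher for 11 of 12 genes (median 0.31), with Tcf7 at the values given and the IL-7 receptor chain Il7r at 142 ± 32.0 and 227 ± 27.6 CPM. Erythroid and platelet markers were higher for 10 of 11 genes (median 1.48), with the near-identical globin genes Hba-a1 at 299 ± 404 and 829 ± 1061 CPM and Hba-a2 at 280.2 ± 376 and 784 ± 1000.1 CPM. Markers of all T cells were lower for 13 of 15 genes (median -0.13), with the receptor constant genes Trbc2 at 2041 ± 198 and 1874 ± 175 CPM and Trbc1 at 1520.5 ± 120.2 and 1389.7 ± 144 CPM. Plasma cell markers did not differ past the threshold (median 0.056, adjusted p = 0.490), with Jchain at 788 ± 746 and 912 ± 498 CPM and Igha at 641 ± 497 and 619 ± 646 CPM.

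By camera these lists rose or fell with adjusted p = 7.9e-05 for B cells, 3.3e-08 for myeloid cells, 7.9e-05 for CD8 T and NK cells, 7.9e-05 for conventional CD4 T cells, 0.0233 for erythroid cells and platelets, and 0.0133 for all T cells. With an estimated correlation the adjusted p was 0.494 for each of these 6 lists. By edgeR 0 members passed adjusted over all genes, and adjusted over the list alone only the platelet gene Gp9 did, at 0.0289, 0 and 0 CPM in WT replicates 1 to 3 and 2.33, 1.09 and 0.647 CPM in KO replicates 1 to 3. DESeq2 called Gp9 over all genes (adjusted p = 0.00490). The scores were 5.88 ± 1.67 in WT and 6.86 ± 0.181 in KO for B cells (exact permutation p = 0.4). They were 3.22 ± 1.17 in WT and 4.11 ± 0.522 in KO for myeloid cells (exact p = 0.3) and 3.87 ± 1.45 in WT and 4.59 ± 2.23 in KO for erythroid cells and platelets (exact p = 0.8). Within pools A and B the score differences were 0.45 and 2.26 for B cells, 0.97 and 1.60 for myeloid cells, and 0.19 and 1.32 for CD8 T and NK cells. They were 0.29 and 0.41 for conventional CD4 T cells and -0.11 and -0.16 for all T cells. The B cell call ended without WT replicate 3 (median -0.092, adjusted p = 0.380), and its median was 0.024 without WT replicate 1, 2.10 without WT replicate 2 and 1.23 with a pool term. It was 1.19 with limma-voom, 1.24 with the replicate number as a block and 1.22 with library quality weights. The myeloid median was 0.48 without WT replicate 1, 2.07 without WT replicate 2, 0.30 without WT replicate 3, 0.32 without KO replicate 2 and 1.72 with a pool term. It was 1.31 with limma-voom, 1.24 with the replicate number as a block and 0.33 with the B cell covariate. For CD8 T and NK cells the call ended without WT replicate 3 (median 0.25, adjusted p = 0.0680) and with the B cell covariate (median 0.26, adjusted p = 0.151), and the median was 1.15 without WT replicate 2 and 0.89 with a pool term. The conventional CD4 call ended without KO replicate 1 (median 0.16, adjusted p = 0.414) and in the 3 of its 12 genes that stand in no other list (median 0.27, adjusted p = 0.216), and its median was 0.55 without KO replicate 3. For all T cells the call ended without WT replicate 1 (median -0.10, adjusted p = 0.203), without WT replicate 3 (median -0.092, adjusted p = 0.0545), without KO replicate 1 (median -0.11, adjusted p = 0.164), without KO replicate 2 (median -0.068, adjusted p = 0.0524) and with the B cell covariate (median -0.070, adjusted p = 0.207). Their median was -0.20 without WT replicate 2 and -0.22 without KO replicate 3. The erythroid call ended without WT replicate 1 (median 0.95, adjusted p = 0.344), without WT replicate 2 (median 1.08, adjusted p = 0.269), without KO replicate 1 (median -0.34, adjusted p = 0.972) and without KO replicate 2 (median 1.78, adjusted p = 0.0755). It also ended with a pool term (median 1.56, adjusted p = 0.0707), with the replicate number as a block (median 1.81, adjusted p = 0.0877), with limma-voom (median 0.96, adjusted p = 0.185) and with library quality weights (median 1.62, adjusted p = 0.0868). The erythroid median was 3.53 without WT replicate 3 and 2.55 with the B cell covariate, and the score difference was 1.99 in pool A and -1.10 in pool B. The plasma cell list passed with a pool term (median 0.97, adjusted p = 0.00164), without WT replicate 2 (median 0.69, adjusted p = 0.00150) and without KO replicate 3 (median 0.39, adjusted p = 0.0395), and in the other direction with the B cell covariate (median -0.26, adjusted p = 0.0213). With an estimated correlation the plasma cell adjusted p was 0.826, and 0.699 with a pool term as well.

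**Figure D3:**
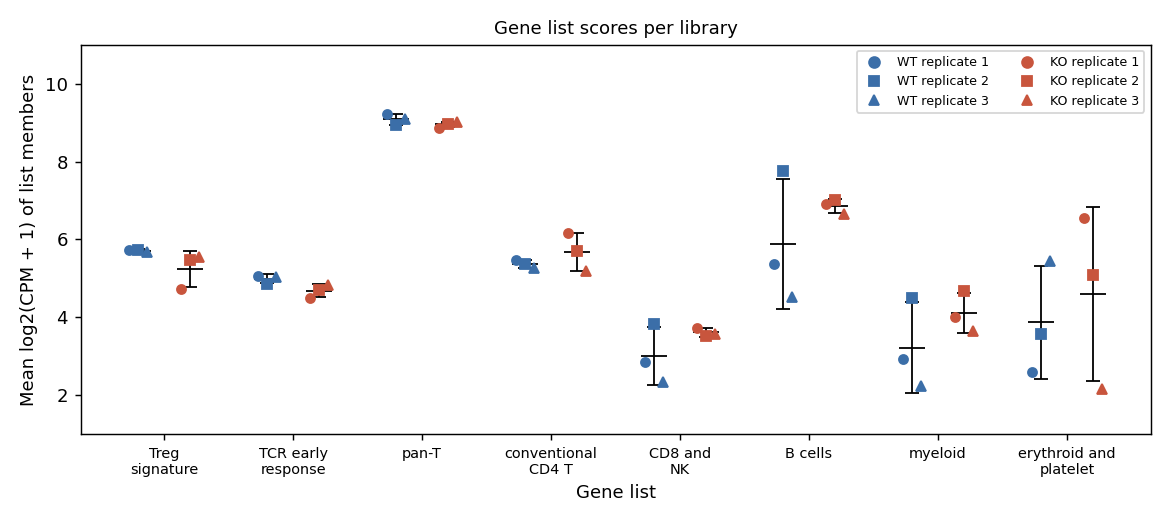
Score (mean log2(CPM + 1) of the members) of 8 gene lists in each library, with WT in blue, KO in red, a symbol per replicate number and black bars for mean ± SD (n = 3). The Treg signature scores of KO lie below those of WT, while the B cell, myeloid and erythroid scores spread over both genotypes.

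No difference between genotypes was detected in the shares that mark RNA quality. Mitochondrial genes took 2.29% ± 0.226 of counts in WT and 2.41% ± 0.0993 in KO, ribosomal protein genes 5.36% ± 0.722 and 5.50% ± 0.489, and the 10 most abundant genes 6.50% ± 0.440 and 6.34% ± 0.311. Haemoglobin genes took 0.107% ± 0.141 in WT and 0.305% ± 0.388 in KO, and immunoglobulin genes 1.46% ± 1.22 and 1.66% ± 0.932. For these shares, library size and genes detected, the exact two-sided permutation p lay between 0.4 and 0.9 (adjusted p = 0.9 for all 7), in a design whose smallest p is 0.1.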

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

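Library quality weights, the removal of genes with identical counts, the B cell covariate, DESeq2 with a pool term, and the pool term with an estimated correlation were tests chosen after the result was seen. The count of 0 genes past the threshold held with edgeR under each normalization, filter, block, pool term and left-out library, with limma-voom, with and without weights, with the B cell covariate and without genes of identical counts, at 478 to 1125 genes with an unadjusted p under 0.05. DESeq2 called 63 of 32774 genes (35 higher, 28 lower), and 404 of 32929 (281 higher, 123 lower) with a term for the inferred pool. Of these genes 9881 had no adjusted p without the pool term and 1520 with it, and could not be called. On 20475 filtered genes simulated with edgeR dispersions and no change DESeq2 called 55 without a pool term. The model with that term was not simulated. Junb passed in both (log2 -0.63), and the cause of the difference between tools was not tested. The median of the Treg signature list lay between -0.66 and -0.19 with a library left out and kept its call there. It was no longer called with an estimated correlation (-0.44), nor with a pool term and an estimated correlation (-0.35), and fry, which tests it against no change, did not call it (-0.44). Of the other lists 15 were called, 8 in genes of 1 list only, 0 with an estimated correlation, 0 with fry, 0 with a pool term and an estimated correlation, and 4 to 18 with a library left out (4 without KO replicate 1). Only 1 suppressor gene stands in no other list (0.097), which is no test of that list. The TGF-beta median was 0.058 in genes of 1 list only, -0.0077 with limma-voom, 0.16 with the B cell covariate and -0.048 to 0.14 with a library left out. The cholesterol median was -0.055 with a pool term, estimated correlation or not, and -0.13 to 0.0099 with a library left out. The plasma cell median was -0.26 with the B cell covariate and -0.29 to 0.69 with a library left out, the resting Treg median -0.024 to 0.32 and the erythroid median -0.34 to 3.53. For these changes the cause was not tested. The main fit did not pair libraries by replicate number, because the labels do not say that the same number marks a shared litter or day. Libraries with the same replicate number also did not all deviate together (r = -0.17, 0.40 and 0.15 over 12527 genes of at least 5 CPM, which are not independent replicates). With the replicate number as a block 0 genes passed (712 unadjusted), the Treg signature median was -0.49 and 13 other lists were called. The spread between libraries limits all of these results, and its weight against that of depth was not tested.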

Other observations

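The tests of other splits of the libraries were planned, and the tests of KO replicate 1 alone, of cells other than T cells, of conventional CD4 T cells, of paralogs and of Prdx2 were chosen after the result was seen, as were the sex-linked and pancreatic genes. Genes of the sex chromosomes set KO replicate 3 apart. Xist, the RNA of the inactive X chromosome, stood at 2.13 CPM there and at 251 to 333 CPM in the other 5 libraries. The Y chromosome genes Ddx3y, Eif2s3y, Kdm5d and Uty stood at 88.8, 68.6, 24.1 and 18.3 CPM in KO replicate 3 and at 0.322 CPM or less in the others. This is the pattern of male cells in KO replicate 3 and of female cells in the other 5 libraries, while the labels give no sex. Sex was thus not balanced between genotypes or within pool B, and no fit held a term for it. Without KO replicate 3 edgeR called 0 genes and the Treg signature median was -0.66. KO replicate 2 had the most counts of pancreatic enzymes, with 26.3 CPM of the amylase gene Amy2a5 (0.376 to 3.67 elsewhere), 12.5 CPM of Cela2a, 5.83 CPM of Try4 and 4.54 CPM of Cpb1. Amy2a5 shares its counts with near-identical copies.

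The lower Treg signature was followed up first. The mean score of KO replicates 2 and 3 lay -0.20 from the WT mean (WT SD 0.0367) with both below the lowest WT library. Lower scores of the list as a whole were thus not confined to KO replicate 1. The rule was set after the scores were seen and the SD rests on 3 libraries, so it cannot decide whether that gap exceeds chance. More cells other than T cells would lower all T cell genes alike, and the median of all-T-cell markers was only -0.13 (quartiles -0.20 and -0.081) against -0.44 for the signature; without KO replicate 1 it was -0.11 against -0.19, too close to decide. Whether more conventional CD4 T cells account for part of it in KO replicates 1 and 2 could not be decided. The scores of conventional CD4 T cell markers in those libraries exceeded the highest WT score. They did so by 0.246 in KO replicate 2 and by more in KO replicate 1. KO replicate 3, in contrast, lay -0.080 from the lowest WT score. Scores of resting Treg genes ran the same way. They were 6.44, 6.41 and 6.40 in WT replicates 1 to 3 and 6.88, 6.59 and 6.25 in KO replicates 1 to 3. The test therefore cannot tell such cells from a higher level of resting Treg genes. Loss of JunB itself was not tested and stays open in all 3, as does the sorting gate, and 9 of the 12 conventional markers stand in other lists. Foxp3 lay -0.37, -0.30 and 0.10 (log2) from the WT mean in KO replicates 1 to 3. The lower list score of KO replicate 3 did not hold for each gene. Foxp3 (39.0 CPM), Il2ra (150 CPM) and Ctla4 (157 CPM) lay within the range of the WT libraries there. Ikzf2 stood at 477 CPM in KO replicate 3, above the highest WT library at 475 CPM.

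The Junb counts left in KO were the next pattern. Of the 50-base words of the Junb transcripts, 0% stand in transcripts of genes other than Prdx2, so reads of paralogs or copies are argued against. Reads of Prdx2 as the whole source are argued against by the slope of Junb on Prdx2 CPM within genotypes, 0.0651 (SE 0.0605), whose upper 95% bound of 0.258 lies below the 0.384 needed. At that bound Prdx2 could still give 36.7 of the 54.7 CPM in KO. Cells that kept Junb, and transcripts left after recombination, are open and were not tested.

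The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. As many genes as the real split (0 with edgeR) came from 10 splits, with 4 in the highest other, and as many DESeq2 calls (63) from 5 splits, with 699 in the highest other. Both highest splits part the libraries by the number in the names of the deposited tables that was taken as the sequencing pool, with 2193 genes at an unadjusted p under 0.05 in edgeR. With so few splits this cannot decide whether the samples differ along that number. What the number marks is not given in the sources used here. By the chi-square per degree of freedom, pairs of libraries within an inferred pool lay between 38.3 and 78.4. Pairs across the pools lay between 48.4 (WT replicate 1 and KO replicate 3) and 142, so the ranges overlap. With a pool term the genotype comparison gave 0 genes by edgeR (933 unadjusted). As many lists as the real split (16) came from 1 split, the real one, with 14 in the highest other, and a Treg signature median as far from 0 (0.44) from 1 split, with 0.36 in the highest other. Camera at the preset correlation called the Treg signature list in every split (largest adjusted p = 0.0331).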
